A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

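Gene expression was measured in Saccharomyces cerevisiae BY4741 and in a pif1 mutant of that strain on 8 spotted 2-colour arrays, each holding 2 RNAs. Per the labels' protocols, cells were grown in rich medium (YPD) at 28 °C to an A660 of 0.6, zinc chloride was added to 5 mM for 1 h where stated, and labelled cDNA was made from 8 ug of total RNA with an oligo(dT) primer. The labels name 4 comparisons of 4 kinds of RNA (wild type or mutant, with or without zinc), with 2 arrays each, numbered 1 and 2, on which the dyes were exchanged. On the zinc arrays (with zinc over without, in each strain) the first-named RNA carried Cy5 on replicate 1, and on the mutant arrays (mutant over wild type, in each medium) it carried Cy3 on replicate 1. The labels do not say whether the numbers stand for separate cultures, so the p-values may measure technical spread only.

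The values analysed were those deposited by the authors as 1 table of log2 ratios, with 1 column per array. Per the labels, spots under 120 um in diameter, or with Cy3 and Cy5 fluorescence below 100 units, were left out before deposit. The scanner software, background correction, normalization and log base of the deposited table are not stated. The log base was taken as 2, and the direction as first-named over second-named RNA on every array, for these reasons: both arrays of each comparison correlated above 0 although their dyes were exchanged, PIF1 lay far below 0 on the mutant arrays, and heat shock genes lay above 0 on the zinc arrays. The scale therefore rests on the size of the values, the direction on these genes, and the authors' centring remains unknown. The column medians were −0.064 and −0.036 for zinc in the wild type, 0.0745 and −0.0365 for zinc in the mutant, −0.033 and −0.013 for the mutant without zinc, and −0.027 and −0.027 for the mutant with zinc. The lowest correlation between 2 arrays was that of wild-type zinc replicate 1 with mutant replicate 2 without zinc (r = −0.365 across 3857 genes). An RNA shared in the same position, as the labels give for these arrays, would push the correlation above 0, so the shared RNA does not account for this value. The direction was kept for the reasons given above.

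The table held 6212 yeast IDs, of which 5519 had a value on at least 1 array, 3857 on all 8 and 693 on none. The arrays held values for 73.3% to 82.4% of the IDs. Each ID was 1 row, so no values were averaged within a gene. Symbols were taken from NCBI's R64 table of yeast genes by locus tag, which matched 5662 IDs. The other 550 keep their ID, 406 of them with a value. Coordinates were not used. Values beyond 16 in size (2, both of PIF1) were taken as placeholders and set to missing.

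Each array was centred on its median. Ratios were tested with limma 3.58.1 under R 4.3.3 (lmFit and eBayes), with 1 coefficient per comparison and a spread pooled over all 8 arrays, for genes with a value on both arrays of a comparison. Benjamini-Hochberg adjustment ran over the genes tested in each comparison, and adjusted p-values under 0.05 passed. The difference in zinc response between the strains was a contrast that averages its estimate from the zinc arrays and its estimate from the mutant arrays, for genes with a value on all 8 arrays. SDs are those of the 2 arrays of a comparison. Because only 2 arrays stand behind each value, their number limits the precision.

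Of 30 gene lists fixed before the data were examined, 29 had at least 1 measured gene. The mitochondrially encoded list had none. Lists with at least 4 tested members were tested with limma's cameraPR (preset correlation between genes of 0.01, two-sided), adjusted over all lists and the 5 contrasts, and again with a correlation estimated from the residuals and with fry. The lists cover the Zap1 zinc regulon, zinc transport, the Aft1 and Aft2 iron regulon, siderophore uptake, iron-sulfur enzymes, the TCA cycle, the retrograde response, the respiratory chain, mitochondrial and cytosolic ribosomal proteins, ribosome biogenesis, oxidative stress, sulfate assimilation, general stress, heat shock chaperones, cell wall integrity, phosphate, copper, glucose-repressed genes, ergosterol, hypoxic mannoproteins, amino acid synthesis, the proteasome, DNA damage, subtelomeric families, a-cell, alpha-cell and sporulation genes, and the auxotrophic markers deleted in BY4741. Some lists share members: the 8 siderophore genes are all in the iron list, and 6 zinc transport genes are in the Zap1 list. The TCA cycle and retrograde lists share 5 genes, and the iron-sulfur list shares 2 with the TCA cycle list and 1 with the retrograde list. Calls of such lists are not separate results.

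Named genes were chosen by a rule fixed before the data were examined: PIF1 first; the 8 highest and 8 lowest means among genes past the threshold with the same sign on both arrays; up to 4 members, by size, of each list called in a comparison, and of the zinc, iron, siderophore, TCA and oxidative stress lists in every comparison; and, where none passed, the 5 highest and lowest genes or up to 2 list members as values. Genes named outside the rule are marked as chosen after their values were seen.

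The steps were tested on simulated data built from the spread of these arrays, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in each comparison. Of genes changed 2-fold, 88.1% (wild-type zinc, 4635 genes), 83.6% (mutant zinc, 4272 genes), 76.1% (mutant without zinc, 4722 genes) and 80.6% (mutant with zinc, 4657 genes) were recovered. Of genes changed 1.5-fold, 41.8%, 34.3%, 49.3% and 25.4% were. False calls made up 8.43%, 7.05%, 7.41% and 6.80% of the simulated calls in that order. The simulation gave each gene 1 spread on all 8 arrays and independent errors. The real within-pair SD was 0.431 for mutant zinc and 0.215 to 0.235 for the others, and same-numbered arrays shared part of their deviation. These rates may therefore not hold for the real arrays, least of all for mutant zinc. A search for displaced IDs, added after the data were seen, recovered a median of 67.5 of 75 moved IDs in 20 simulated runs, and its highest summed gain without a moved run was 4.

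The alternatives were a dye term, the experiment number as a block, no centring, arrays scaled to one median absolute deviation, quantile normalization, other rules for the genes tested, a loop model with 3 coefficients, dye-swapped arrays averaged first and then fitted with the loop model, which leaves 1 residual degree of freedom, robust moderation, each comparison fitted alone, an adjusted p under 0.01, a fold rule with no test (at least 2-fold, and 1.5-fold on each array), each array left out in turn, and for lists the estimated correlation and fry. Alternatives added after the data were seen use the zinc arrays or the mutant arrays alone, exchange strain names or zinc labels between comparisons, and leave out or move a run of displaced IDs. Intensities, background and array positions were not used here.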

Results

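Transcript levels were compared between budding yeast of strain BY4741 and a pif1 mutant, which lacks a DNA helicase of the nucleus and the mitochondria, before and after 1 h in 5 mM zinc chloride. The series concerns the zinc tolerance of this mutant. RNAs were hybridised in pairs on 8 arrays, 2 per comparison with exchanged dyes: wild type with zinc against wild type, pif1 with zinc against pif1, pif1 against wild type without zinc, and pif1 against wild type with zinc. In that order the arrays held values for 4823 and 4801, 4580 and 4556, 4753 and 5082, and 4678 and 5119 IDs. Across genes, the 2 arrays of a comparison correlated at 0.868, 0.573, 0.586 and 0.439. Their within-pair SD was 0.235, 0.431, 0.215 and 0.225, while the tests pooled 1 spread over all 8 arrays. The numbers of genes past the threshold are therefore not directly comparable between comparisons. Genes are not independent replicates. All values are log2 ratios of the first-named over the second-named RNA.

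PIF1 (YML061C), the deleted gene, was far lower in the RNA labelled pif1 on the mutant arrays. It was at −4.90 as deposited on replicate 2 without zinc (29.5-fold lower after centring) and at −3.72 on replicate 2 with zinc (12.9-fold lower). On replicate 1 of both comparisons it held placeholders (values beyond 16 in size, −99 on the array with zinc), and it had no value on the 4 zinc arrays. Its neighbour OGG1, which encodes a DNA glycosylase, was also lower: −1.19 ± 0.22 (SD, n = 2, limma adjusted p = 0.0173) without zinc and −1.58 ± 0.21 (n = 2, adjusted p = 0.00687) with zinc. Of the other neighbours, chosen after the values were seen, MFT1 (−0.46 and −0.18) and NTE1 (−0.10 and 0.01) did not pass.

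PIF1 was also used to read the direction of the ratios, so its sign is no independent check of the channel, and it checks nothing on the zinc arrays. Heat shock genes were used in the same way on the zinc arrays. The signs of the heat shock list and the overlapping general stress list there are therefore no independent check either. Which mutant arrays held zinc-treated RNA was looked at through the genes that had a value. Of 405 genes higher after zinc in both zinc comparisons, 99.5% and 99.8% had a value on the mutant arrays labelled without zinc, against 90.4% and 97.8% on those labelled with zinc. For 390 genes lower after zinc the shares were 94.9% and 97.2% against 97.2% and 97.7%. For 2337 genes past the threshold in neither they were 96.4% and 98.0% against 95.9% and 98.3%. Of 51 genes at least 4-fold higher after zinc on the arrays labelled wild type, 98.0% and 100% had a value on the arrays labelled without zinc, and 64.7% and 80.4% on those labelled with zinc. The mutant comparisons are therefore described by their labels, as arrays labelled without or with zinc.

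**Figure D1:**
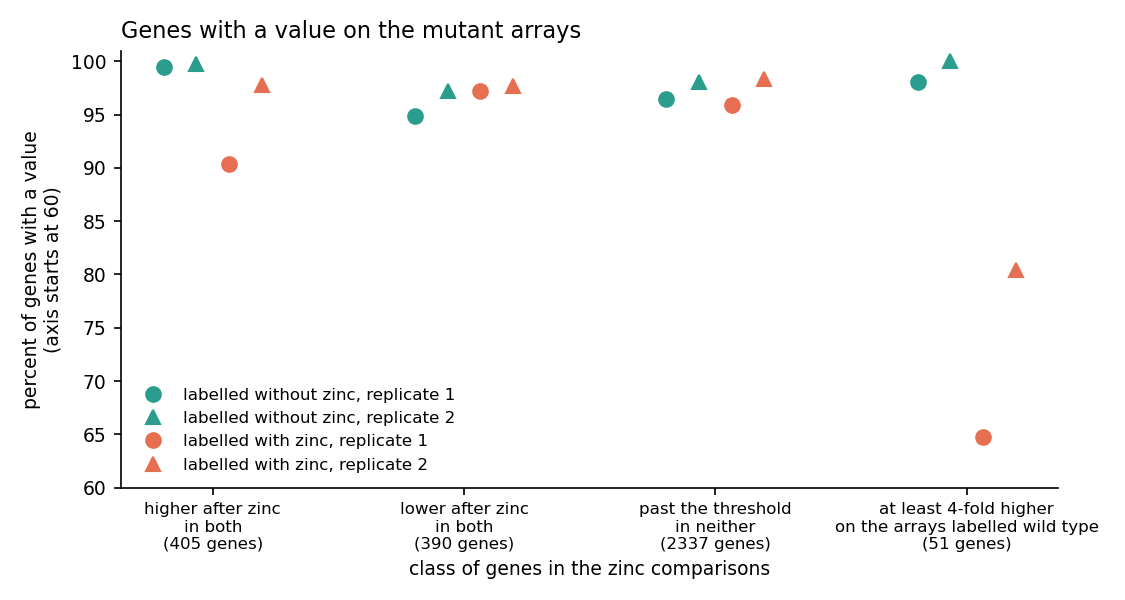
Percent of genes with a value on each of the 4 mutant arrays (vertical axis, not starting at 0), for classes of genes set by the zinc comparisons (horizontal axis); colours give the label and shapes the replicate. Of the 51 genes at least 4-fold higher after zinc, 64.7% and 80.4% had a value on the arrays labelled with zinc and 98.0% and 100% on those labelled without.

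On both zinc arrays labelled wild type, 75 neighbouring IDs of the table (YMR176W to YMR250W) differed from the other arrays in the same way. Over this run, having a value on these 2 arrays correlated between −0.0468 and 0.0651 with having one on the other 6 arrays, and between 0.618 and 0.814 when set against the next ID. The search chose the run by this presence of values, so these correlations follow in part from the choice. Its summed gain was 22 here and 2 to 3 in the other comparisons. The zinc responses were not used in the search. The zinc responses of the 2 strains correlated at −0.0780 across 40 genes of the run, at 0.914 across 51 genes against the next ID, and at 0.824 outside the run. The run holds 21 of the genes called on the arrays labelled wild type, including RPL36A, DFG5 and ZRC1, and their values there are marked below as lying in the run.

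**Figure D2:**
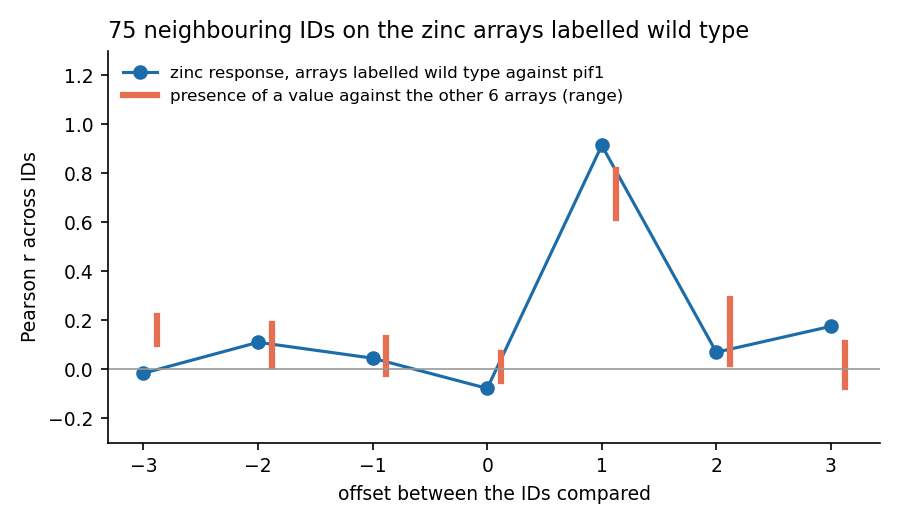
Pearson correlation over 75 neighbouring IDs (vertical axis) at each offset between the IDs compared (horizontal axis). The line shows the zinc response on arrays labelled wild type against that on arrays labelled pif1, with 0.914 at an offset of 1 and −0.0780 at 0. The bars show the range of correlations of presence, by which the run was chosen, with the other 6 arrays.

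The first comparison asked how the wild type responded to zinc. Stress genes were among those with the highest ratios, and enzymes of amino acid synthesis among those with the lowest. HSP26 (YBR072W), a small heat shock protein, rose by 6.64 ± 0.37 (SD, n = 2, 99.5-fold, adjusted p = 2.9e-06). TSL1, a subunit of trehalose synthase, rose by 4.47 ± 0.79 (n = 2, adjusted p = 7e-05), and HSP12 by 4.06 ± 0.36 (n = 2, adjusted p = 1.6e-05). The lowest were enzymes of branched-chain amino acid, glutamate and lysine synthesis that carry an iron-sulfur cluster: LEU1 (YGL009C) fell by 3.71 ± 0.21 (n = 2, adjusted p = 2.9e-06), and GLT1 (−3.64 ± 0.50) and LYS4 (−2.72 ± 0.06) fell as well. ZRT1, the high-affinity zinc importer, fell by 2.21 ± 0.33 (n = 2, adjusted p = 0.000131). The other highest genes were YOR121C (5.05), NQM1 (3.93), MET28 (3.68), HMX1 (3.67) and GCY1 (3.58), and the other lowest included ILV3 (−2.56), IRC7 (−2.40) and MLS1 (−2.08).

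In all, 1403 of 4635 genes passed (681 higher, 722 lower), 217 of them at least 2-fold higher and 142 at least 2-fold lower. When either array was left out, 441 (without replicate 1) or 477 (without replicate 2) passed, with the spread of the lone array taken from the other comparisons. With all arrays scaled to 1 spread or 1 distribution, 713 or 690 passed. The list test called 13 lists.

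Of 38 general stress genes, 35 rose and 0 fell (median 1.81, cameraPR adjusted p = 1.5e-23), and 35 rose when adjusted over the list alone. Beside HSP26, TSL1 and HSP12, PGM2, a phosphoglucomutase, rose by 3.24 ± 0.13. Of 27 heat shock chaperones, 18 rose and 0 fell (median 0.58, adjusted p = 3e-08, also 18 adjusted over the list alone), among them HSP30 (2.69 ± 0.14), SSA4 (2.30 ± 2.02) and SSE2 (2.14 ± 0.26). Of 39 oxidative stress genes, 19 rose and 2 fell (median 0.55, adjusted p = 1.2e-06; 22 and 2 adjusted over the list alone; adjusted p = 0.156 with an estimated correlation). ECM4, a glutathione transferase, rose by 2.60 ± 0.20, the peroxiredoxins TSA2 by 2.05 ± 0.30 and PRX1 by 1.70 ± 0.08, and AAD6 by 1.62 ± 0.12. Of 35 proteasome genes, 11 rose and 1 fell (median 0.34, adjusted p = 0.00115; 12 and 1 adjusted over the list alone; adjusted p = 0.0581 with an estimated correlation), with UFD1 at 0.85 ± 0.04 and RPN7 at 0.68 ± 0.34. PRE2 (0.62) and PRE10 (0.57) were the next.

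Most measured genes of iron uptake rose. All 6 measured siderophore genes rose (median 2.08, adjusted p = 1.8e-06, 6 adjusted over the list alone). FIT3 (3.15 ± 0.42), FIT1 (2.32 ± 0.09) and FIT2 (2.19 ± 0.08), cell wall proteins that retain siderophore-bound iron, led with the transporter ARN2 (1.97 ± 0.10). Of 25 Aft1 and Aft2 targets, 18 rose and 1 fell (median 0.78, adjusted p = 1.5e-07; 19 and 1 adjusted over the list alone; adjusted p = 0.0798 with an estimated correlation), with the heme oxygenase HMX1 at 3.67 ± 0.08. Of 23 genes of sulfate assimilation, 10 rose and 0 fell (median 0.29, adjusted p = 0.00045, 10 adjusted over the list alone). MET28 (3.68 ± 1.25), STR3 (3.40 ± 0.60), MET16 (1.66 ± 0.34) and MET3 (1.48 ± 0.61) led.

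Among 9 genes of zinc transport, 2 rose and 3 fell (the same counts adjusted over the list alone), and the list was not called (median −0.04, adjusted p = 0.582). The importers ZRT1, FET4 (−1.81 ± 0.22) and ZRT2 (−1.70 ± 0.25) fell, and COT1, a vacuolar zinc and cobalt transporter, rose by 1.03 ± 0.11. ZRC1, another vacuolar zinc transporter, was at 0.72 ± 0.40 (n = 2, adjusted p = 0.0149), but it lies in the run of 75 IDs, and moving the run by 1 ID turned it to −0.74. The Zap1 regulon had 2 genes higher and 4 lower of 18 (the same adjusted over the list alone), with a median of 0.07, a mean of −0.27 and a test direction below 0 (adjusted p = 0.582).

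Most genes of ribosome synthesis fell. Of 90 ribosome biogenesis genes, 76 fell and 1 rose (median −0.89, adjusted p = 1.5e-23; 81 and 1 adjusted over the list alone). The helicases DBP2 (−1.89 ± 0.20) and MAK5 (−1.34 ± 0.19) and the nucleolar NSR1 (−1.58 ± 0.02) fell, and NOP1, the nucleolar fibrillarin, was the gene that rose (2.50 ± 0.06). Of 126 cytosolic ribosomal protein genes, 96 fell and 1 rose (median −0.74, adjusted p = 3.3e-22; 117 and 1 adjusted over the list alone; adjusted p = 0.345 with an estimated correlation). RPP0 (−1.05 ± 0.22), RPL5 (−1.02 ± 0.20) and RPS9B (−1.01 ± 0.17) fell most. The gene that rose, RPL36A (1.75 ± 0.41), lies in the run of 75 IDs, and moving the run turned it to −0.66. Of 46 amino acid synthesis genes, 13 fell and 4 rose (median −0.31, adjusted p = 0.00803; 14 and 4 adjusted over the list alone; adjusted p = 0.646 with an estimated correlation), led by LYS4, ILV5 (−1.48 ± 0.18), LEU9 (−1.44 ± 0.17) and BAT1 (−1.27 ± 0.33).

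The test also called 3 further lists. Of 29 respiratory chain genes, 9 rose and 0 fell (median 0.27, adjusted p = 0.0119, 9 adjusted over the list alone; adjusted p = 0.525 with an estimated correlation), such as ATP15 (1.07 ± 0.42), ATP16 (0.78 ± 0.07), COX13 (0.77 ± 0.01) and TIM11 (0.75 ± 0.03). Of 23 cell wall integrity genes, 7 rose and 1 fell (median 0.45, adjusted p = 0.00351, the same adjusted over the list alone; adjusted p = 0.315 with an estimated correlation), such as the glucan synthase GSC2 (1.10 ± 0.21), PIR1 (0.86 ± 0.28) and SED1 (0.85 ± 0.19). The gene that fell, DFG5 (−1.18, n = 2), lies in the run, and moving the run turned it to 0.34. Of 17 phosphate genes, 6 rose and 1 fell (median 0.26, adjusted p = 0.0276, the same adjusted over the list alone; adjusted p = 0.132 with an estimated correlation), with PHM8 at 1.99 ± 0.08, GPP2 at 1.48 ± 0.35, PHO5 at 1.25 ± 0.04 and PHO11 at 0.81 ± 0.22. The phosphate call ended without replicate 2 (adjusted p = 0.0593). Of 18 TCA cycle genes, 4 rose and 2 fell, and the list was not called (adjusted p = 0.648). LSC2 (0.95), MDH1 (0.93) and CIT1 (0.76) were among those that rose.

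The second comparison asked how the pif1 mutant responded to zinc. The stress genes HSP26 (3.31 ± 0.05, n = 2, 9.93-fold, adjusted p = 8.3e-05), HSP31 (3.08 ± 0.38) and DDR48 (2.93 ± 0.10) were among the highest, with YMR173W-a (3.03), RGI1 (2.90), YML131W (2.79) and PGM2 (2.73). GPX2, a glutathione peroxidase, rose by 2.61 ± 0.41 (n = 2, adjusted p = 3.1e-05). Its mean on the arrays labelled wild type was −0.14. Among the lowest were LYS4 (−3.20 ± 0.16, n = 2, 9.19-fold, adjusted p = 1.3e-05), IRC7 (−2.89), FET4 (−2.36), LEU1 (−2.34 ± 0.10), DBP2 (−2.27), YGL041C (−2.20 ± 2.58) and ADE57 (−1.96).

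Here 1338 of 4272 genes passed (661 higher, 677 lower), 157 at least 2-fold higher and 186 at least 2-fold lower, and 13 lists were called. Among 4086 genes tested in both zinc comparisons, 405 were higher in both, 390 lower in both and 8 opposite, where independent calls would give 95.2, 104 and 199. The zinc responses of the strains correlated at 0.811 across 3857 genes. With this comparison's 2 arrays fitted alone, 526 genes passed, and with all arrays scaled to 1 spread or 1 distribution, 413 or 420.

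Of 38 general stress genes, 34 rose and 0 fell (median 1.34, adjusted p = 2.6e-19, 34 adjusted over the list alone), with TFS1 at 2.50 ± 0.50 and HSP12 at 2.44 ± 0.47. Of 28 heat shock chaperones, 13 rose and 2 fell (median 0.40, adjusted p = 0.000521; 14 and 2 adjusted over the list alone), with HSP30 at 2.31 ± 0.23, BTN2 at 1.63 ± 0.83 and the disaggregase HSP104 at 1.49 ± 0.42. Of 37 oxidative stress genes, 22 rose and 0 fell (median 0.67, adjusted p = 9.9e-09; 25 adjusted over the list alone; adjusted p = 0.0696 with an estimated correlation). Beside GPX2, the superoxide dismutase SOD1 (1.98 ± 0.62), PRX1 (1.83 ± 0.17) and the thioredoxin TRX2 (1.58 ± 0.38) rose. Of 36 proteasome genes, 12 rose and 1 fell (median 0.33, adjusted p = 0.00169; 14 and 1 adjusted over the list alone; adjusted p = 0.0696 with an estimated correlation). RPN13 (0.72), RPN8 (0.72) and PRE2 (0.68) rose and CDC48 (−0.75) fell.

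Of 9 zinc transport genes, 5 fell and 0 rose (median −0.57, adjusted p = 0.0041, 5 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation). FET4 (−2.36 ± 0.27), ZRT1 (−1.96 ± 0.26), ZRT2 (−1.45 ± 0.34) and ZRC1 (−0.79 ± 0.31) were 4 of them, and the list's call ended without replicate 2 (adjusted p = 0.0738). The Zap1 regulon had 7 genes lower and 4 higher of 17 (9 and 4 adjusted over the list alone) and was not called (median −0.44, adjusted p = 0.156). Its member TSA1, a peroxiredoxin, rose by 1.47 ± 1.08. Of 24 iron regulon genes, 7 rose and 1 fell (median 0.26, adjusted p = 0.0163, the same adjusted over the list alone; adjusted p = 0.577 with an estimated correlation). HMX1 (2.44 ± 0.16) and the copper chaperone ATX1 (1.36 ± 0.57) rose and the ferric reductase FRE1 (−1.40 ± 0.19) fell. Of 6 siderophore genes, FIT2 (1.34 ± 0.63), FIT3 (1.07 ± 0.74) and ARN1 (1.02 ± 0.34) rose (median 0.66, adjusted p = 0.0296, 3 adjusted over the list alone; adjusted p = 0.348 with an estimated correlation). Without replicate 1 both calls ended (adjusted p = 0.417 and 0.183), and the iron median was −0.02.

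Among mitochondrial genes, 2 lists were called above 0. Of 24 respiratory chain genes, 14 rose and 0 fell (median 0.49, adjusted p = 4.7e-05, 14 adjusted over the list alone; adjusted p = 0.144 with an estimated correlation), including ATP7 (0.92 ± 0.63), CYT1 (0.90 ± 0.28), QCR8 (0.88 ± 0.22) and ATP16 (0.76 ± 0.64). Of 53 mitochondrial ribosomal protein genes, 11 rose and 0 fell (median 0.20, adjusted p = 0.0167; 3 adjusted over the list alone; adjusted p = 0.591 with an estimated correlation), including MRPL23 (0.80 ± 0.45), MRPS12 (0.72 ± 0.59), RSM10 (0.66 ± 0.27) and MRP8 (0.62 ± 0.52). The mitochondrial ribosomal call ended without replicate 1 (adjusted p = 0.106). Of 16 TCA cycle genes, 5 rose and 1 fell, and the list was not called (adjusted p = 0.57). MDH1 (1.20 ± 0.62), CIT1 (0.88 ± 0.16) and LSC1 (0.66 ± 0.30) were among those that rose.

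Of 83 ribosome biogenesis genes, 66 fell and 1 rose (median −0.94, adjusted p = 2.2e-22; 70 and 1 adjusted over the list alone), with DBP2, MAK5 (−1.90 ± 0.05), DIP2 (−1.82 ± 0.06) and NSR1 (−1.81 ± 0.32). Of 120 cytosolic ribosomal protein genes, 21 fell and 0 rose (median −0.33, adjusted p = 5.4e-07; 6 adjusted over the list alone; adjusted p = 0.686 with an estimated correlation). RPS0B (−1.03 ± 0.26), RPL7B (−0.82 ± 0.37), RPL8B (−0.81 ± 0.38) and RPL5 (−0.80 ± 0.52) were lowest, and without replicate 2 the list lay at −0.02 and its call ended (adjusted p = 0.757). Of 48 amino acid synthesis genes, 14 fell and 0 rose (median −0.34, adjusted p = 6.6e-05, 14 adjusted over the list alone; adjusted p = 0.348 with an estimated correlation), with LYS4, LEU9 (−1.79 ± 0.39), ILV5 (−1.67 ± 0.63) and TRP5 (−1.25 ± 0.09). Of 24 cell wall integrity genes, 5 rose and 0 fell (median 0.43, adjusted p = 0.00351; 2 adjusted over the list alone; adjusted p = 0.324 with an estimated correlation). KDX1 (1.14 ± 0.27), SED1 (0.93 ± 0.73), DFG5 (0.62 ± 0.48) and SVS1 (0.56 ± 0.48) rose. The amino acid call ended without replicate 2 (adjusted p = 0.0752) and the cell wall call without replicate 1 (adjusted p = 0.264).

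**Figure D3:**
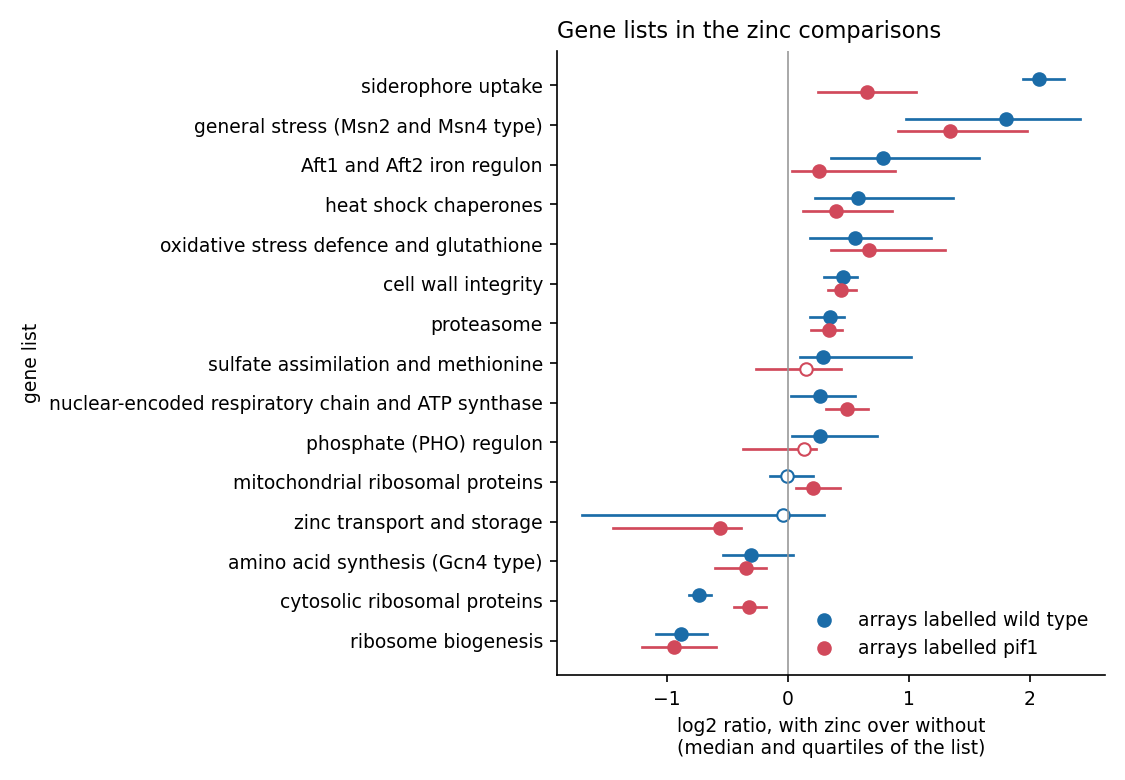
Median log2 ratio with zinc over without (horizontal axis) of each gene list called in a zinc comparison (vertical axis), with bars from the lower to the upper quartile of its genes; filled points passed the list test and open points did not. General stress genes had medians of 1.81 and 1.34 on the arrays labelled wild type and pif1, and ribosome biogenesis genes −0.89 and −0.94.

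The third comparison asked what the mutation changed without added zinc, on the arrays labelled so. Some TCA cycle genes were among those higher in the mutant: the aconitase ACO1 (YLR304C) by 1.67 ± 0.19 (n = 2, 3.18-fold, adjusted p = 0.00125) and the isocitrate dehydrogenase subunits IDH2 by 1.44 ± 0.22 (n = 2, adjusted p = 0.0051) and IDH1 by 1.27 ± 0.07 (n = 2, adjusted p = 0.00609). The peptide transporter PTR2 rose by 1.71 ± 0.01 and LEU1 by 1.59 ± 0.07 (both n = 2, adjusted p = 0.00125). Lower in the mutant were YLR236C (−2.41 ± 0.31), YLR162W (−1.97), YLR122C (−1.95), YLR012C (−1.80) and YLR161W (−1.61), followed by HMX1 (−1.24 ± 0.26), OGG1 and HSP31 (−1.11 ± 0.30). The other highest genes were YOR135C (1.81), SUT1 (1.71 ± 1.01), PUF3 (1.56), OSI1 (1.54) and BSC1 (2.83-fold).

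Here 96 of 4722 genes passed (68 higher, 28 lower), 32 at least 2-fold higher and 10 at least 2-fold lower, and 11 lists were called. With this comparison's 2 arrays fitted alone, 592 genes passed. After quantile normalization 436 passed (252 higher, 184 lower), with the replicate number as a block 291 (202 higher, 89 lower), with dye-swapped arrays averaged first and fitted with the loop model 11, and 1 or 13 passed without replicate 1 or 2. Leaving out 1 array of another comparison, which changes only the pooled spread, gave 54 (wild-type zinc arrays), 242 (mutant zinc arrays) or 58 (the other mutant arrays).

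Of 17 retrograde response genes, which mitochondrial defects activate, 5 rose and 0 fell (median 0.20, adjusted p = 0.00011, 5 adjusted over the list alone). They included ACO1, IDH1, IDH2 and the regulator RTG3 (0.95 ± 0.16). Of 19 TCA cycle genes, 4 rose (median 0.13, adjusted p = 0.000676, 4 adjusted over the list alone; adjusted p = 0.0798 with an estimated correlation), ACO1, IDH1 and IDH2 among them. Of 24 iron-sulfur genes, ACO1, LEU1, LYS4 (1.34 ± 0.37) and the ribosome recycling factor RLI1 (0.85 ± 0.24) rose and 0 fell (median 0.20, adjusted p = 0.000309, 6 higher adjusted over the list alone). Of 59 mitochondrial ribosomal protein genes, MRPS18 (0.74 ± 0.12) rose over all genes and 18 adjusted over the list alone (median 0.35, adjusted p = 6.8e-14).

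Stress lists lay lower, with few genes past the threshold. Of 29 heat shock chaperones, 3 fell and 1 rose (median −0.42, adjusted p = 1.3e-07; 15 and 2 adjusted over the list alone). ERO1 (−0.93 ± 0.02), CPR6 (−0.70 ± 0.09) and FES1 (−0.68 ± 0.02) fell, and SSA3 (0.83 ± 0.04) rose. Of 39 general stress genes, MSC1 (−0.72 ± 0.04) fell and 0 rose (median −0.25, adjusted p = 0.000164; 7 lower and 2 higher adjusted over the list alone). Of 23 sulfate assimilation genes, MET16 (−0.98 ± 0.03) and the transporter MUP3 (−0.94 ± 0.04) fell (median −0.23, adjusted p = 2.6e-05, 6 adjusted over the list alone). The proteasome list lay lower (median −0.21, adjusted p = 0.00025), although its member past the threshold, the assembly chaperone POC4, rose by 1.08 ± 0.11 (1 of 38, also adjusted over the list alone).

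The other 3 called lists lost their call with an estimated correlation. The iron regulon lay at −0.14 (0.116 with the loop model of 3 coefficients, which turned its direction), with HMX1 its 1 lower gene of 25 (2 adjusted over the list alone, adjusted p = 0.0296, and adjusted p = 0.655 with an estimated correlation). The oxidative stress list lay at −0.16 (adjusted p = 0.00463, and adjusted p = 0.525 with an estimated correlation), where CCP1, cytochrome c peroxidase, rose by 1.03 ± 0.05 and the transporter FLR1 fell by 0.69 ± 0.03, 1 each of 38, also adjusted over the list alone. Amino acid synthesis lay at −0.15 (adjusted p = 0.0324, and adjusted p = 0.686 with an estimated correlation). LYS4 rose and ARG4 (−0.66 ± 0.13) fell, 1 each of 46 (2 higher and 3 lower adjusted over the list alone). The oxidative and amino acid calls ended without replicate 2 (adjusted p = 0.0558 and 0.169). The 6 siderophore genes had 0 past the threshold and 1 lower adjusted over the list alone (median −0.34, adjusted p = 0.0861), with FIT2 at −0.71 and FIT3 at −0.47. Of 9 zinc transport genes 0 passed, also adjusted over the list alone, with ZRT2 at 0.55 and ZRT1 at 0.32. In the Zap1 regulon IZH1 fell by 0.62 ± 0.04, with 1 higher and 1 lower gene of 16 adjusted over the list alone.

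The fourth comparison asked what the mutation changed with zinc, on the arrays labelled so. DAN1 (YJR150C), a cell wall mannoprotein of anaerobic growth, was higher in the mutant by 3.31 ± 0.06 (n = 2, 9.93-fold, adjusted p = 0.00647) and TIR4, of the same kind, by 1.87 ± 0.55 (n = 2, adjusted p = 0.0264). HSP26 rose by 2.07 ± 0.84 (n = 2, adjusted p = 0.00913), and HUG1, a DNA damage gene, by 1.84 ± 0.09 (n = 2, adjusted p = 0.00913). GPX2 fell by 2.56 ± 0.01 (n = 2, 5.91-fold, adjusted p = 0.000552), and ROX1, the repressor of hypoxic genes, by 1.40 ± 0.16 (n = 2, adjusted p = 0.00507). The other highest were FIT3 (1.56), YER076C (1.52), FIT1 (2.82-fold) and the drug pump PDR5 (1.48), and the other lowest OGG1, TPO4 (−1.19), MUP3 (−1.04), YOR225W (−1.03), HSP31 (−1.02) and REE1 (−0.89).

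Here 55 of 4657 genes passed (46 higher, 9 lower), 19 at least 2-fold higher and 7 at least 2-fold lower, and 13 lists were called. With this comparison's 2 arrays fitted alone, 267 genes passed. After quantile normalization 317 passed (224 higher, 93 lower), with the replicate number as a block 122 (96 higher, 26 lower), with dye-swapped arrays averaged first and fitted with the loop model 0 by limma (457 had an unadjusted p under 0.05 before averaging), and 2 or 3 passed without replicate 1 or 2. Leaving out 1 array of another comparison gave 18 (wild-type zinc arrays), 127 (mutant zinc arrays) or 19 (the other mutant arrays). Among 4468 genes tested in both mutant comparisons, 14 were higher in both, 5 lower in both and 0 opposite, where independent calls would give 0.616, 0.0504 and 0.370. The ratios correlated at 0.491 across 3857 genes. The labels do not say whether the comparisons used the same RNA extracts, so their calls are not taken as independent.

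Of 17 retrograde response genes, 5 rose and 0 fell (median 0.13, adjusted p = 1.2e-06, 5 adjusted over the list alone). PDR5 (1.48 ± 0.17), IDH1 (1.17 ± 0.17), ACO1 (1.13 ± 0.16) and IDH2 (1.11 ± 0.13) were among them. Of 18 TCA cycle genes, IDH1, ACO1 and IDH2 rose and 0 fell, and the list was not called (adjusted p = 0.594, 3 adjusted over the list alone). Of 61 mitochondrial ribosomal protein genes 0 passed, also adjusted over the list alone, while the list lay at 0.27 (adjusted p = 9.5e-12). MRPS5 was at 0.82 and MRP10 at 0.61. Of 16 hypoxic genes and mannoproteins, DAN1, TIR4 and the mitochondrial ATP carrier AAC3 (0.77 ± 0.12) rose and ROX1 fell (median 0.62, adjusted p = 3.6e-06; 10 higher and 1 lower adjusted over the list alone). Of 6 siderophore genes, FIT3 (1.56 ± 0.44), FIT1 (2.82-fold, both arrays higher) and ARN2 (1.20 ± 0.06) rose (median 1.04, adjusted p = 9.3e-11, 5 adjusted over the list alone).

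These 3 genes were also those that rose among 25 iron regulon genes (median 0.25, adjusted p = 0.000129; 8 higher and 2 lower adjusted over the list alone; adjusted p = 0.277 with an estimated correlation). With the loop model the iron median was 0.037 and the test pointed below 0 (adjusted p = 0.958). Of 17 DNA damage genes, HUG1 and the ribonucleotide reductase RNR3 (1.09 ± 0.06) rose and 0 fell (median 0.18, adjusted p = 0.0138, 2 adjusted over the list alone; adjusted p = 0.378 with an estimated correlation). In the heat shock list HSP26 and SSA3 (1.34 ± 0.05) rose, while the median of its 29 genes was −0.16, the mean −0.02 and the test direction below 0 (adjusted p = 0.037; 2 higher and 1 lower adjusted over the list alone; adjusted p = 0.109 with an estimated correlation). The oxidative stress list lay at −0.10 with GPX2 its 1 lower gene of 36, also adjusted over the list alone (adjusted p = 0.000412, and adjusted p = 0.345 with an estimated correlation). The sulfate list lay at −0.13 with MUP3 its 1 lower gene of 20, also adjusted over the list alone (adjusted p = 0.0276, and adjusted p = 0.0506 with an estimated correlation). Without replicate 1 or 2 the heat shock call ended (adjusted p = 0.365 and 0.0693), as did the sulfate call (0.0585 and 0.0741), and the DNA damage call ended without replicate 1 (0.122).

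In 4 further called lists 0 genes passed, also adjusted over the list alone. They were the respiratory chain (28 genes, median −0.16, adjusted p = 0.00501, and 0.431 as the adjusted p with an estimated correlation), cytosolic ribosomal proteins (124 genes, −0.09, adjusted p = 0.00946, and 0.839), amino acid synthesis (46 genes, −0.13, adjusted p = 0.0364, and 0.686) and the proteasome (38 genes, −0.11, adjusted p = 0.0148, and 0.2). Their members farthest from 0 included CYT1 (−0.67), QCR7 (−0.42), CPA1 (0.58), LYS21 (−0.56), POC4 (0.56), PUP1 (−0.27), RPS1A (−0.28) and RPS18B (−0.22). Without replicate 2 these 4 calls ended (adjusted p = 0.149, 0.737, 0.481 and 0.201 in the same order), and the ribosomal median turned to 0.05. It was at 0.0218 with the loop model. Of 19 Zap1 targets and 9 zinc transport genes 0 passed, also adjusted over the list alone, with TSA1 at −0.96, FET4 at 0.44 and PHO84 at 0.27.

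**Figure D4:**
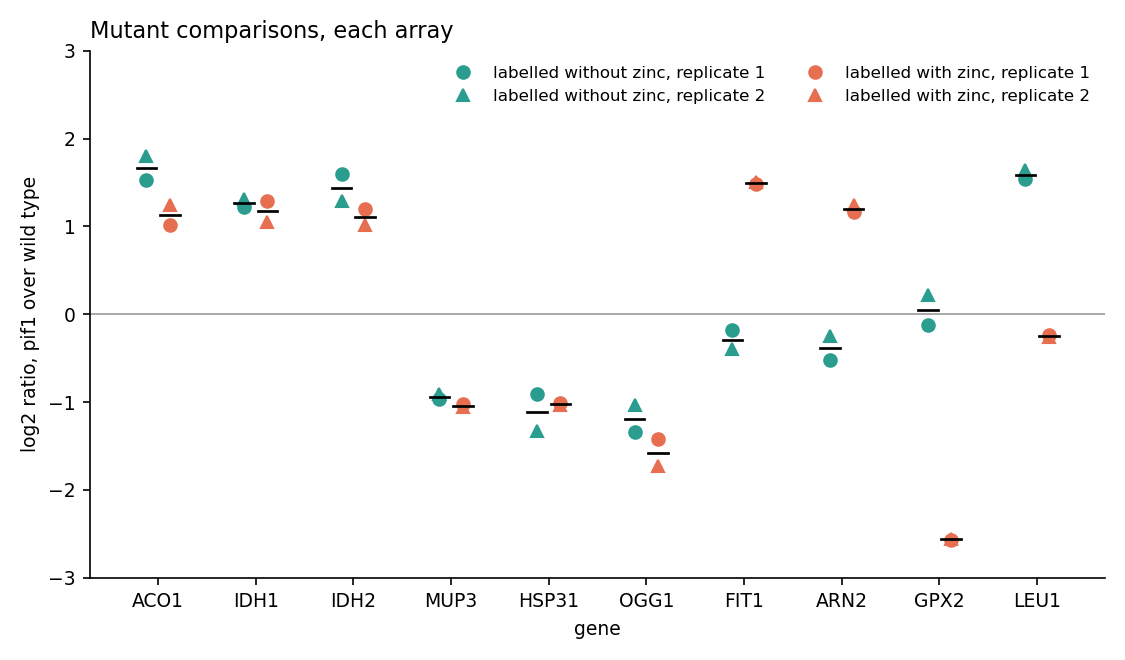
Log2 ratio of pif1 over wild type (vertical axis) on each of the 4 mutant arrays for 10 named genes (horizontal axis); colours give the label, shapes the replicate and black lines the mean of 2 arrays. ACO1, IDH1 and IDH2 were between 1.11 and 1.67 in both comparisons, while FIT1 was at −0.29 on the arrays labelled without zinc and 2.82-fold higher on those labelled with zinc.

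The calls that held with an estimated correlation were general stress, heat shock, siderophore uptake, sulfate assimilation and ribosome biogenesis for zinc in the wild type, and general stress, heat shock and ribosome biogenesis for zinc in the mutant. For the mutation without zinc they were the iron-sulfur, retrograde, mitochondrial ribosomal, sulfate, general stress, heat shock and proteasome lists. With zinc they were the siderophore, retrograde, mitochondrial ribosomal and hypoxic lists. For the retrograde and sulfate lists the estimated correlation (0.00831 and 0.00643) lay below the preset 0.01, so before adjustment it was no stricter test of them. The mitochondrial ribosomal list then had cameraPR adjusted p-values of 0.0083 without zinc and 0.0209 with zinc. Fry did not call the proteasome list without zinc (fry adjusted p = 0.0554), nor the mitochondrial ribosomal (0.0980) and hypoxic (0.125) lists with zinc.

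The last comparison asked whether zinc acted differently in the 2 strains. With all 8 arrays, limma called 0 of 3857 genes, and 230 had an unadjusted p under 0.05 (lowest adjusted p = 0.128). The 5 highest, none past the threshold, were YLR162W (1.07, SE 0.19, adjusted p = 0.165), MLS1 (1.06), YLR161W (1.05), YLR012C (1.05) and YLR122C (1.02). The 5 lowest were RKR1 (−1.55, SE 0.21, adjusted p = 0.128), which lies in the run of 75 IDs, LYS4 (−0.96), YBL100C (−0.87), ARE1 (−0.85) and YFL032W (−0.83). Without mutant zinc replicate 1 or 2, 2 or 13 genes passed.

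The contrast joins 2 estimates of the same difference, 1 from the zinc arrays and 1 from the mutant arrays. Across genes they correlated at −0.251 (95% interval of a bootstrap over genes −0.321 to −0.183). Taken alone, the zinc arrays called 16 genes (7 higher) and the mutant arrays 9 (4 higher). HSP26 was at −3.32 from the zinc arrays (SE 0.35, n = 4 arrays, limma adjusted p = 0.00242) and at 2.86 from the mutant arrays (SE 0.35, adjusted p = 0.00834). GPX2 was at 2.74 (SE 0.23, adjusted p = 0.00145) and −2.61 (adjusted p = 0.00228). These separate estimates were added after the data were seen, and 5 of the 16 genes lie in the run of 75 IDs.

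The test called 2 lists. Cytosolic ribosomal proteins lay at a median of 0.16 (117 genes, adjusted p = 7e-09, and adjusted p = 0.686 with an estimated correlation), with RPS4A at 0.40. Without mutant zinc replicate 1 it lay at −0.02 and the call ended (adjusted p = 0.486). Zinc transport lay at −0.19 (9 genes, adjusted p = 0.0296, and adjusted p = 0.291 with an estimated correlation), with ZRC1 at −0.81 and COT1 at −0.26. That call was lost when the run of IDs was left out (median −0.15, adjusted p = 0.201), and without mutant zinc replicate 2 (adjusted p = 0.286), replicate 1 of the mutant comparison without zinc (0.225) or replicate 2 of that with zinc (0.101). In both lists 0 genes passed, and ZRC1 passed adjusted over the list alone. The Zap1 (median 0.02, mean −0.07), iron (−0.09), siderophore (−0.13), TCA cycle (−0.11) and oxidative stress (0.07) lists were not called. Their members farthest from 0 included MCD4 (−0.55), FIT2 (0.37), TIS11 (−0.34), ARN1 (−0.24), KGD2 (−0.21), TSA2 (−0.29) and GTT1 (0.27). The joined medians average estimates of opposite sign: −1.41 (zinc arrays) and 1.59 (mutant arrays) for siderophore uptake, and −0.54 and 0.26 for the iron regulon. They therefore do not show that the strains responded alike.

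In other lists the genes went both ways or few of them passed. Of 23 iron-sulfur genes, 8 fell and 4 rose after zinc in the wild type (8 and 5 adjusted over the list alone, adjusted p = 0.159), with LEU1, GLT1 and LYS4 the lowest, and of 21 in the mutant 6 fell and 2 rose (7 and 3 adjusted over the list alone). In the mutant their median was 0.05, while the mean was −0.38 and the test pointed below 0 (adjusted p = 0.482). The retrograde list was not called after zinc (adjusted p = 0.702 and 0.916), with 4 genes higher and 2 lower of 17 in the wild type (4 and 3 adjusted over the list alone) and 3 higher and 2 lower of 14 in the mutant (the same adjusted over the list alone). The sulfate list was not called after zinc in the mutant, with 5 higher and 4 lower of 21 (the same adjusted over the list alone, median 0.15, adjusted p = 0.634). The hypoxic list was not called after zinc, with 3 higher and 3 lower of 13 in the wild type and 3 higher and 5 lower of 13 in the mutant (3 and 5, and 3 and 6, adjusted over the list alone). In the DNA damage list 4 of 16 rose and 1 fell in the wild type (5 and 3 adjusted over the list alone), and 1 rose and 4 fell in the mutant (the same adjusted over the list alone). The mitochondrial ribosomal list was not called after zinc in the wild type (2 higher and 2 lower of 58, 1 and 0 adjusted over the list alone, adjusted p = 0.861), nor the phosphate list in the mutant (4 higher and 3 lower of 18, the same adjusted over the list alone, adjusted p = 0.766). On the mutant arrays labelled without zinc, the respiratory chain (31 genes, adjusted p = 0.543) and cytosolic ribosomal proteins (124 genes, adjusted p = 0.648) had 0 genes past the threshold, also adjusted over the list alone, and ribosome biogenesis 1 higher of 88 (the same adjusted over the list alone, adjusted p = 0.624). On those labelled with zinc, general stress had 2 higher and 0 lower of 31 (5 and 0 adjusted over the list alone, adjusted p = 0.133), and ribosome biogenesis 0 of 87, also adjusted over the list alone (adjusted p = 0.0537). Neither the cell wall list (adjusted p = 0.623 and 0.648) nor the phosphate list (0.258 and 0.124) was called in a mutant comparison. Median, mean and test also differed in sign in the TCA cycle list on the arrays labelled with zinc (median −0.06, mean 0.12) and the glucose-repressed list after zinc in the mutant (median −0.21, mean 0.04). With smaller values, signs also differed in at least 1 comparison in the ergosterol, subtelomeric, a-cell, sporulation, DNA damage, mitochondrial ribosomal, zinc transport and, in the difference between strains, the heat shock and iron-sulfur lists.

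The remaining lists were called in no comparison. Of the copper genes, 3 of 9 rose and 2 fell in the wild type and 2 of 7 rose and 2 fell in the mutant after zinc, and 0 passed in either mutant comparison (the same adjusted over the list alone, except for 1 lower on the arrays labelled with zinc). Of the glucose-repressed genes, 2 of 18 rose and 3 fell in the wild type (the same adjusted over the list alone), and 3 of 17 rose and 2 fell in the mutant (3 and 3 adjusted over the list alone). Of the ergosterol genes, 0 of 24 rose and 5 fell in the wild type, and 4 of 22 rose and 3 fell in the mutant (the same adjusted over the list alone). Of the subtelomeric families, whose copies can share probes, 3 of 18 rose and 3 fell in the wild type (the same adjusted over the list alone) and 1 of 17 rose in the mutant (0 adjusted over the list alone). Sporulation genes, which haploid cells hardly express, had 1 of 8 higher after zinc in the wild type and 0 in the other 3 comparisons, with medians from −0.08 to 0.15. Mating type a genes had 2 of 7 higher in the wild type and 1 of 6 higher and 1 lower in the mutant after zinc, and 0 passed in the mutant comparisons. Alpha-cell genes and the deleted auxotrophic markers had too few members for a list test. Of the former, 1 of 2 rose in the wild type and 1 of 3 in the mutant, and of the latter 0 passed in the 4 comparisons, with medians from −0.16 to 0.08.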

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

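All tests of explanations in this part, and the separate use of the zinc arrays and the mutant arrays, were chosen after the results were seen.

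The difference in zinc response between the strains can be computed from the zinc arrays or from the mutant arrays. With correct labels and the same RNAs on all arrays, both should give the same values apart from error. By limma, 16 genes passed on the zinc arrays and 9 on the mutant arrays, and the 6 genes past in both had opposite signs. HSP26 was at −3.32 and 2.86, GPX2 at 2.74 and −2.61, FIT1 at −2.02 and 1.78, ARN2 at −1.91 and 1.59, LEU1 at 1.38 and −1.84, and CCP1 at 1.32 and −1.44. Without the run of 75 IDs described below, 5 of these 6 passed in both, and CCP1 was at an adjusted p of 0.0679 on the zinc arrays. Of the genes at least 0.5, 1 and 1.5 from 0 on the mutant arrays, 131 of 198, 17 of 23 and 9 of 9 had the opposite sign on the zinc arrays. Gene lists differed in the same way, with medians on the zinc and mutant arrays of −1.41 and 1.59 for siderophore uptake, −0.54 and 0.26 for the iron regulon, −0.45 and 0.33 for general stress, −0.18 and 0.17 for heat shock, and −0.29 and 0.25 for the phosphate regulon. These were the 5 lists past in both sets with an estimated correlation.

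Across genes the 2 estimates correlated at −0.251 (95% bootstrap interval −0.321 to −0.183). The bootstrap resampled genes, which are not independent replicates, so its interval does not measure the spread between cultures. The labels do not say whether the comparisons used the same RNA extracts. Only if they did would the value argue against every array holding the RNAs its label names. An exchange of the strain names of the zinc comparisons would turn the sign. It would leave the mutant arrays as labelled, yet of the 405 genes higher after zinc in both strains, 37 had both values on the mutant arrays labelled without zinc and not on those labelled with zinc, and 0 the reverse. A candidate explanation is that the zinc labels of the 2 mutant comparisons were exchanged: the 26 genes with values on both mutant arrays labelled without zinc and neither labelled with zinc had a median zinc response of 1.57. Under this hypothesis the mutant values reported with zinc and without zinc would trade places. It would also put RNA shared by the mutant zinc arrays and the mutant arrays labelled without zinc in the same position. Their correlation was −0.263, but the sign that shared RNA gives was simulated for unchanged genes only, so this value cannot decide. The explanation stays open.

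Of the 405 genes higher after zinc in both strains, 90.4% and 97.8% had a value on the mutant arrays labelled with zinc, fewer than the 99.5% and 99.8% on those labelled without. Bright spots left out before deposit might do this, but 93.9% of the cytosolic ribosomal protein genes, which are among the most abundant transcripts, had a value on the lower of those arrays. Fewer spots of every kind might do it too, but 95.9% of the genes past the threshold in neither zinc comparison had a value on the lower of those arrays. On the other array their share was 98.3%, close to the 97.8% of the 405 genes, so there these 2 classes do not argue against it. Of the 51 genes at least 4-fold higher after zinc, 80.4% had a value on that array. Complete values on only 1 of the mutant comparisons went with the direction of the zinc response (37 and 0 genes among those higher, 0 and 9 among those lower, Fisher's exact test, two-sided, p = 9.1e-10). The test counted genes, which are not independent replicates, so its p-value does not measure the spread between arrays. On the arrays labelled with zinc, 366 of the 405 genes had a value on replicate 1 and 396 on replicate 2. The losses among these genes therefore lay mostly on replicate 1. A biological explanation, such as zinc acting on these genes for a shorter time in those cultures, was not tested.

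The third pattern is the run of 75 neighbouring IDs. A candidate explanation is that values were entered 1 ID too early on both zinc arrays labelled wild type, since at the next ID the zinc response of the run correlated at 0.914 with that on the arrays labelled pif1. A strain difference in the response of these genes would leave presence in place, and over the run the highest correlation of presence with any of the other 6 arrays was 0.0651. The run was chosen by presence, so this low value follows in part from the choice and cannot decide against a strain difference. The zinc response at the next ID was not used in the choice. RPL36A (difference in zinc response −1.94, not tested), DFG5 (1.80) and ZRC1 (−1.50) lie in the run, and their differences between the strains rest on it.

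AAD6 rose on both arrays labelled wild type and was below 0 on both labelled pif1, a difference of −1.93 that was not tested because it lacked values on mutant arrays. LYS4 differed between the mutant comparisons by −1.44, GSC2 by 1.47 and ROX1 by −1.61, each past the threshold on the mutant arrays. In the contrast that joins all 8 arrays, the zinc transport list (median −0.19) and the cytosolic ribosomal protein list (median 0.16) differed between the strains, and neither call held with an estimated correlation.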

How the results depend on the processing

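The alternatives that use the zinc or the mutant arrays alone, exchange labels, or leave out or move the run of IDs were chosen after the data were seen, as was leaving out an array of another comparison. The others were fixed before the data were examined.

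Named genes kept their direction and side of the threshold in 3983 comparisons with an alternative, lost the call in 392, gained one in 41 and reversed in 3. List tests kept their direction and call in 733, lost the call in 95 and turned direction in 4, where the list median did not always turn. Counts of genes stayed within 1.5 times in 66 and moved in 52, and counts of lists in 64 and 16. Except where stated, the cause was not tested.

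Scaling the arrays to one median absolute deviation gave 713 genes (zinc, wild type), 413 (zinc, mutant), 440 (mutant without zinc) and 371 (mutant with zinc), and quantile normalization 690, 420, 436 and 317. An adjusted p under 0.01 gave 692, 680, 17 and 13, as a stricter threshold must give fewer. The fold rule gave 358, 325, 49, 31 and, for the difference between strains, 5. With each comparison fitted alone, 526 (zinc, mutant), 592 (mutant without zinc) and 267 (mutant with zinc) passed. Averaging dye-swapped arrays first, which also needs the loop model and leaves 1 residual degree of freedom, gave 11 (mutant without zinc) and, by limma, 0 (mutant with zinc, where 457 genes had an unadjusted p under 0.05 before averaging). The loop model gave 63 (mutant without zinc).

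Leaving out 1 array gave 441 to 1961 genes for zinc in the wild type (441 and 477 without its own replicate 1 and 2), 1 to 242 for the mutant without zinc, 2 to 127 for the mutant with zinc, and 0 to 13 for the difference between strains (2 or 13 without mutant zinc replicate 1 or 2). Fewer arrays remain in each such fit, and where 1 array of an arm remained it was assumed to vary like the other comparisons.

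Taking the replicate number as a block gave 291 genes for the mutant without zinc, 122 with zinc and 1 for the difference between strains. The same-numbered arrays' differences correlated at 0.438 to 0.552 across genes in the 6 pairs of comparisons, also where the labelled dyes were opposite. A dye effect that followed the labels would give values below 0 in pairs with opposite labelled dyes, yet these lay at 0.438 to 0.515. Either the labelled dyes or the source of the shared deviation is therefore uncertain, and the dye term may not remove it. What the number stands for is unknown.

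For the difference between strains, the zinc arrays alone gave 16 genes and the mutant arrays alone 9. Exchanging strain names on the zinc comparisons gave 28 and exchanging zinc labels of the mutant comparisons 28, since both exchanges change the same sign. The zinc arrays alone gave 7 genes with the run of IDs left out and 7 with it moved by 1. The correlation of the 2 estimates was −0.131 on experiment 1 arrays and −0.144 on arrays with the first RNA labelled Cy3.

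With an estimated correlation 5, 3, 7, 4 and 0 lists were called for zinc in the wild type, zinc in the mutant, the mutant without zinc, the mutant with zinc and the difference. Fry called 6 (mutant without zinc), 2 (with zinc) and 0 (difference). The loop model called 8 (mutant with zinc) and 1 (difference), leaving out 1 array 7 to 14 (mutant with zinc, 7 without replicate 2) and 1 to 5 (difference), and leaving out or moving the run of IDs 1 and 1 (difference).

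The loop model turned the iron list to 0.116 (mutant without zinc) and lowered it to 0.037 (with zinc, where the test's direction turned and the median did not). It turned the cytosolic ribosomal list to 0.0218 (with zinc), which was −0.23 without replicate 1 and 0.05 without replicate 2. Moving the run of IDs by 1 turned RPL36A to −0.66, DFG5 to 0.34 and ZRC1 to −0.74 for zinc in the wild type, by its construction. All IDs were unique, so averaging repeated IDs was not run. Signal over background was not used here, so its limit on weak spots is unknown.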

Other observations

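The first paragraph restates values of comparisons fixed before the data were examined. The other comparisons and tests in this part were chosen after the results were seen.

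In both strains 1 h of zinc raised most general stress genes and lowered most ribosome biogenesis genes and the iron-sulfur enzymes LEU1 (−3.71 and −2.34) and LYS4 (−2.72 and −3.20). HSP26 rose by 6.64 in the wild type and by 3.31 in the mutant, and the zinc importer ZRT1 fell by 2.21 and 1.96. In the mutant the retrograde genes ACO1 (1.67 and 1.13), IDH1 (1.27 and 1.17) and IDH2 (1.44 and 1.11) were higher on the arrays labelled without and with zinc, so this effect is the same for either assignment of the zinc labels. MUP3 (−0.94 and −1.04) and HSP31 (−1.11 and −1.02) were lower in both.

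Across 3857 genes, the wild type's zinc response correlated with the mutant's effect at −0.330 on the arrays labelled without zinc and at −0.0289 on those labelled with zinc. The mutant's zinc response did so at −0.263 and −0.111. Of the genes past the threshold in both, 44 of 51, 22 of 33, 25 of 32 and 8 of 14 went in opposite directions in that order. Independent calls among all genes tested in both would give 13.3, 7.91, 12.1 and 7.35 opposite genes. These are not parts of the same totals: for the first pair they would also give 8.99 genes higher in both and 4.06 lower in both. In a simulation of unchanged genes, RNA shared in the same position gave a correlation above 0 (0.50) and RNA shared in opposite positions 1 below 0 (−0.50). As labelled, RNA is shared in the same position in the first and last of these pairs and in opposite positions in the other 2. With the zinc labels of the mutant comparisons exchanged, the positions would be the reverse. These 4 values, all below 0, have the simulated signs throughout under neither assignment. Many genes changed on these arrays, which the simulation leaves out, so the 4 values cannot decide between the assignments.

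RTS2 differed between replicates in every comparison, with centred values on replicate 1 and 2 of 2.16 and −1.90, 1.39 and −4.19, 1.23 and −2.69, and 1.95 and −2.09. Values as deposited, before centring, were exactly identical on both arrays of a comparison for 8, 6, 3 and 8 genes.

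Of 28 genes lower in the mutant without zinc, 9 have systematic names that begin with YLR, against 365 of 4722 tested. The pattern was seen among the lowest genes and is not tested on other data, and 1 or 5 genes were lower without replicate 1 or 2. YLR012C, YLR122C, YLR161W and YLR162W were also lower after zinc on the arrays labelled wild type (−1.23, −1.19, −1.15 and −1.19).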
